A study of Mus musculus with 6 samples.

How the data were processed

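Total RNA of sorted calvarial osteocytes was measured on 6 Affymetrix GeneChip arrays with biotin-labelled RNA, 3 from mice without estrogen receptor alpha (ERα) in osteocytes and 3 from control littermates. Per the labels' protocols, cells of fractions 4 to 6 out of 6 digestions of 30 min were sorted for green fluorescence, and labelling started from 5 µg of RNA. The labels give all mice as female C57/BL6 animals of 10 to 12 days. The series design states that RNA was not pooled, while the extraction protocol speaks of pooled calvarial tissue. The labels call the arrays biological replicates and the controls wild type, while the extraction protocol names floxed mice. Whether controls carried Cre is not given in the sources used here, so an effect of Cre is not separated from that of ERα loss. The labels give 3 mice per genotype. If tissue of several of them was combined before sorting, arrays of a genotype can share tissue, and the p-values do not measure the spread between mice.

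The authors deposited 1 value per probe set and array as an intensity on a linear scale. GCOS, the array maker's operating software, is the tool named in the submitters' processing notes, with no version. The background correction, the summary of probes into a probe set, and the scaling target are not given in the sources used here. Detection calls were not used here, so no bound was set on dim probe sets. Array medians of the deposited signal were 22.7, 20.5 and 18.7 in control replicates 1, 2 and 3, and 21.3, 20.2 and 28.6 in knockout replicates 1, 2 and 3. Between 38.6% and 46.9% of the signals on an array lay under 16. The number of arrays limits the precision.

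From these values log2(signal + 16) was computed, so a fold change is on that scale and understates the change of dim genes. The rule written before the data were examined covered linear tables with array medians above 50 or near 1. The medians here lay between these cases, and the form for linear signals was used. Because the array medians differed by 0.36 on the log2 scale, above the limit of 0.25 set in advance, the arrays were quantile normalised. Of 45101 probe sets, 64 control probe sets were left out. The platform annotation listed 1 gene symbol and gene identifier for 34945 probe sets and several symbols for 932, which were not named. A further 9160 probe sets are unnamed here. Gene identifiers of 34741 probe sets were found in the RefSeq gene table and took its current symbol. The probe set with the highest mean stood for its gene among 18193 genes, of which 9010 had 2 or more probe sets. The lowest 40% of genes by mean over all arrays, 7277 genes under a log2 level of 5.37, were left out, and 10916 were tested.

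Knockout was compared with control by limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend, 2-sided, and Benjamini-Hochberg adjustment at 0.05. All 6 arrays entered 1 fit with no covariate. Of 42 gene lists of bone cells, signalling, cell states and other cell types, with 741 distinct genes, 675 had a probe set and 554 were tested. The 38 lists with at least 3 tested genes went through limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists. The same lists were tested by camera with an estimated correlation and by fry, whose directional test asks whether the genes of a list move on balance 1 way and whose mixed test asks whether they change in either direction. Neither fry test compares a list with other genes. A list's level on an array is the mean of its tested genes after each gene was centred over the 6 arrays. A gene had separated groups when all 3 values of 1 group lay above all 3 of the other, which chance gives in 10% of genes.

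The genes named in the text were chosen by a rule. It took Esr1, then in each direction the 10 largest differences past the threshold with separated groups. With fewer than 5 past the threshold, 5 genes with the smallest p and separated groups were taken instead, passing over symbols of unnamed transcripts. It also took 14 bone and Wnt genes, and up to 4 members of each list with the smallest p. Runx2, Bglap and Ddx3y had no probe set of a single gene and were not analysed here. Fgf23 fell under the level filter. Myl1, Ogn, Col11a2 and further list members given as past the threshold without control replicate 2 lie outside this rule and were named after their values were seen. The pair Mdk and Sostdc1 was listed because the study's own report is recalled to have singled it out, so it is no independent evidence.

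The steps were tested on simulated data with 10916 genes, 3 arrays against 3 and 200 changed genes in each of 20 runs. The fit recovered 31.4% of genes changed by 1.5-fold, 72.1% of those changed by 2-fold and 94.5% of those changed by 4-fold, with 6.9 false calls per run. A list of 20 genes shifted by 0.3 was called in 100% of runs. The simulated genes varied independently of each other. On the real arrays the estimated correlation was 0.73 for chondrocyte and 0.92 for interferon genes, against -0.001 for axon guidance genes. The simulated shares need not hold for genes that vary together. Alternatives chosen in advance were offsets of 1 and 64, the deposited scaling, subtraction of array medians, no level filter, a filter of 60%, the mean of all probe sets, each probe set on its own, a variance without trend or with robust estimation, array weights, the replicate number as a block, each array left out in turn, a minimum of 1.5-fold, and a threshold of 0.1. Added after seeing the data were the muscle list level or the macrophage list level as a covariate, the deposited scaling without control replicate 2, and camera with an estimated correlation with each array left out in turn.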

Results

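Osteocytes, the cells embedded in bone matrix, were compared between mice without ERα, the estrogen receptor encoded by Esr1, in osteocytes and control littermates, with 3 arrays per genotype. The cells carried green fluorescent protein under the Dmp1 promoter. They came from the calvariae of young female mice and were sorted through a gate that held 10% to 15% of cells in marked mice and 0.8% to 1.0% in unmarked mice. The design asks which osteocyte transcripts differ when ERα is absent. The controls are labelled wild type, while the extraction protocol names floxed mice, and whether they carried Cre is not given in the sources used here. A difference between the groups can therefore hold an effect of Cre beside that of ERα loss. Across the tested genes, which are not independent replicates, Pearson's r on the log2 scale lay between 0.984 and 0.988 for pairs of knockout arrays, between 0.939 and 0.969 for pairs of control arrays, and between 0.961 and 0.975 for pairs of 1 control and 1 knockout array. Control replicate 2 had 0.974 with knockout replicate 1 and 0.939 with control replicate 1, so the control arrays did not stand together apart from the knockout arrays.

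Esr1 was read by 3 probe sets, which differed. The brightest had log2 levels of 6.97, 6.89 and 6.80 in control replicates 1, 2 and 3 and of 6.63, 6.60 and 6.82 in knockout replicates 1, 2 and 3. The difference was -0.20 ± 0.12 (SE, limma, adjusted p = 0.572), and the groups overlapped. Under the deposited scaling the difference was -0.06, while the median of all genes moved from -0.01 to 0.14. The dimmest had deposited signals of 20.2, 11.6 and 13.3 in control arrays and of 1.0, 1.0 and 2.5 in knockout arrays. Its log2 difference of -0.86 ± 0.13 (SE) came with separated groups, below the level filter, so it entered no count. An exact permutation test of 3 arrays against 3 cannot give a 2-sided p under 0.1. For the remaining probe set the difference was -0.13 ± 0.21 (SE). The labels name neither the deleted part of Esr1 nor the position of these probe sets, so Esr1 does not check the labels. Xist, the RNA of the inactive X chromosome, had log2 levels of 12.42 ± 0.13 in control and 12.54 ± 0.10 in knockout arrays (SD, n = 3 each). The Y-linked genes Eif2s3y, Kdm5d and Uty had mean levels between 4.21 and 4.66 in both groups. The labels give females only.

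Cartilage matrix genes stood highest in the knockout arrays among the 38 tested gene lists: 13 of 14 chondrocyte markers were higher, with Cnmd 4.71-fold, Col9a3 3.33-fold and Acan 2.72-fold above control. Wnt ligands and receptors, matrix genes and growth factors lay above control by medians of 0.18, 0.11 and 0.22 on the log2 scale. Without control replicate 2 the Wnt and growth factor medians were 0.10 and 0.13, and without knockout replicate 3 the matrix median was 0.21. Interferon-induced genes and pericyte and smooth muscle genes lay below control by medians of -0.49 and -0.36, which depended on single arrays. The interferon median was -1.13 without control replicate 1, -0.31 without control replicate 2, -0.08 without control replicate 3 and -0.24 without knockout replicate 3. The pericyte median was -0.21, -0.79 and -0.11 without control replicates 1, 2 and 3. Genes of the bone cell itself went both ways, with Dkk1 at -0.70 and Dmp1 at -0.30, and Alpl at 0.42. Phex and Col1a1 lay at -0.03 ± 0.08 and -0.05 ± 0.07 (SE). Both were above 0 under the deposited scaling (0.14 and 0.09), where the median of all genes was 0.14. None of these genes, nor any other, passed the threshold in limma with all 6 arrays.

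By limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, and 0 passed 0.1. The smallest adjusted p was 0.120. At an unadjusted p under 0.05 there were 639 higher and 512 lower genes, where 545.8 in all are given by chance. Groups were separated for 1008 higher and 847 lower genes, 17.0% of those tested against 10% by chance. Without control replicate 2, 86 genes were higher and 212 lower past 0.05. Leaving out any other single array gave 0 higher and 0 lower genes. Control replicate 2 had far less muscle RNA than the other controls. The 212 lower genes held 4 of the 14 tested skeletal muscle markers and 6 of the 9 pericyte and smooth muscle markers. With the deposited scaling, 30 genes were higher and 0 lower, and the median of all genes moved from -0.01 to 0.14.

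The 5 genes per direction with the smallest p and separated groups fell short of the threshold. Shisa3, a membrane protein that modulates Wnt and FGF signalling, had a log2 level of 6.57 ± 0.45 in control and 8.50 ± 0.22 in knockout arrays (SD, n = 3 each, limma adjusted p = 0.120), 3.81-fold higher. Slc47a1, an exporter of organic cations, was 3.68-fold higher, and Bnc2, a zinc finger protein, 2.32-fold higher, each at the same adjusted p. Acan, the core protein of aggrecan, had the same adjusted p, and Crispld1 was 1.73-fold higher (limma adjusted p = 0.133). Sorbs2, a cytoskeletal adaptor, had 9.95 ± 0.04 in control and 8.94 ± 0.21 in knockout arrays (SD, n = 3 each, limma adjusted p = 0.120). Rgs5, a regulator of G protein signalling found in pericytes, had 13.15 ± 0.05 and 12.56 ± 0.10 (SD, n = 3 each, limma adjusted p = 0.120). Kctd12b, Zbed5 and the chloride channel gene Ano1 differed by -0.85, -0.74 and -0.56 (limma adjusted p = 0.183 for each). All 4 probe sets of Rgs5 were lower, by -0.59 to -1.10, and both of Shisa3 were higher. The other 3 probe sets of Sorbs2 lay within -0.10 and 0.03, those of Bnc2 at 0.64 and 0.06, and that of Ano1 at -0.21 ± 0.13 (SE). All 10 genes passed 0.05 without control replicate 2, and Shisa3, Slc47a1, Acan and Bnc2 also with the deposited scaling.

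**Figure D1:**
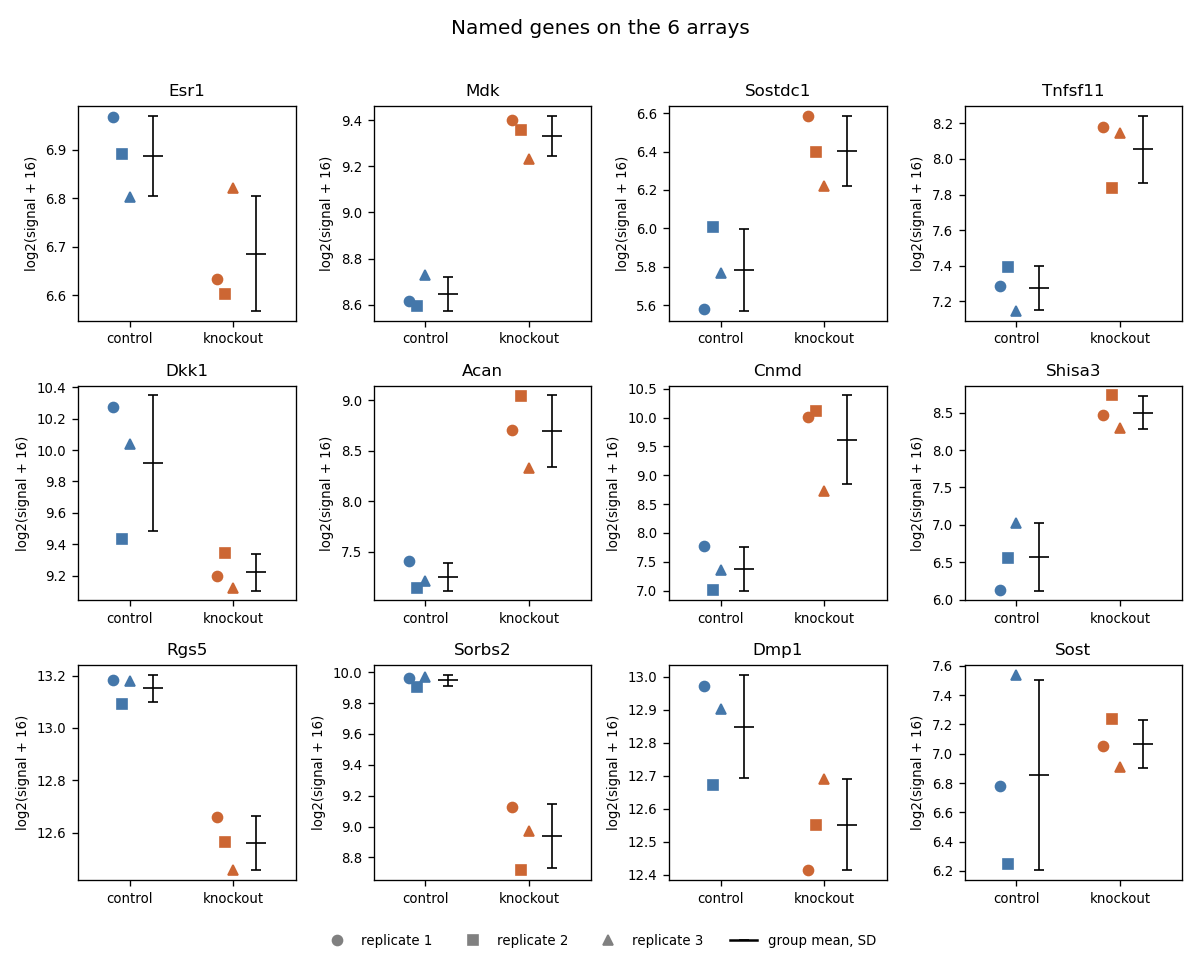
Level of 12 named genes on each array, as log2(signal + 16) after quantile normalisation, with control and knockout on the horizontal axis, 1 point per array, and bars for the group mean and SD (n = 3). Mdk, Tnfsf11, Acan, Cnmd, Shisa3 and Sostdc1 lay above control on all knockout arrays, Rgs5, Sorbs2 and Dkk1 lay below, and Esr1, Dmp1 and Sost overlapped, with none past the threshold.

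Osteocyte markers were lower for 8 and higher for 3 of 11 tested genes, with a median of -0.09 (camera with a preset correlation, adjusted p = 0.129). With the deposited scaling this median was 0.06, below that of all genes. The list was called lower without control replicate 2 (median -0.13, adjusted p = 0.0115, and adjusted p = 0.433 with an estimated correlation), and also with array weights (-0.12, adjusted p = 0.0441), while its median was 0.01 without control replicate 3. In each fixed list 0 members passed over all genes tested, and among osteocyte markers 0 also passed adjusted over the list alone. Dkk1, a secreted Wnt inhibitor, had 9.92 ± 0.43 in control and 9.22 ± 0.12 in knockout arrays (SD, n = 3 each, limma adjusted p = 0.349), and passed without control replicate 2 (-0.93, adjusted p = 0.0134), as did Fbln7 (-0.76, adjusted p = 0.0439). The list's level in control replicates 1, 2 and 3 (0.10, -0.24 and 0.28) moved with that of skeletal muscle genes (2.00, -3.36 and 1.87) and of pericyte and smooth muscle genes (0.44, -0.50 and 0.64). In knockout replicates 1, 2 and 3 it did not follow muscle, at -0.07, 0.02 and -0.11 against -0.58, -0.77 and 0.84. Dmp1, whose promoter drove the marker, differed by -0.30 ± 0.10, Sost, which encodes sclerostin, by 0.21 ± 0.30, and Mepe by 0.45 ± 0.30 (SE). Sost differed by -0.09 and Mepe by 0.09 without control replicate 2, and by 0.55 and 0.68 without control replicate 3. Ptprz1 and Irx5 differed by -0.21 and -0.17. Fgf23, the phosphate-regulating hormone of osteocytes, was under the level filter, at 4.30 in control and 4.53 in knockout arrays. Osteoblast genes were lower for 13 and higher for 5 of 18, with a median of -0.07 (camera, adjusted p = 0.211), and 0 passed adjusted over the list alone. With the deposited scaling this median was 0.08, below that of all genes. Alpl, alkaline phosphatase, differed by 0.42 ± 0.11 and passed without control replicate 2 (limma adjusted p = 0.0341). Serpinf1 differed by -0.13 ± 0.06 (0.00 with the deposited scaling), and Sp7, an osteoblast transcription factor, by -0.17 ± 0.10 (SE). Mineralisation and phosphate genes were higher for 7 and lower for 5 of 12, with none past the threshold adjusted over the list alone and a median of 0.08 (camera, adjusted p = 0.551).

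Osteoclast regulation genes were higher for 8 and lower for 6 of 14, with a median of 0.04 (camera, adjusted p = 0.237). Of these only Tnfsf11, which encodes the osteoclast cytokine RANKL, passed adjusted over the list alone, against 0 over all genes. Its level was 7.28 ± 0.12 in control and 8.05 ± 0.19 in knockout arrays (SD, n = 3 each, limma adjusted p = 0.183), 1.71-fold higher, and it passed without control replicate 2 (adjusted p = 0.0283). Its other probe set differed by 0.36 ± 0.23 (SE). Tnfrsf11b, the decoy receptor of RANKL, differed by 0.22 ± 0.18 (SE), by 0.39 without control replicate 1 and by 0.06 without control replicate 3. Osteoclast markers were higher for 6 and lower for 3 of 9, with a median of 0.04 (camera, adjusted p = 0.147). The list was called without control replicate 2 (0.26, adjusted p = 0.0476, and adjusted p = 0.433 with an estimated correlation). It was also called with the deposited scaling (0.15, against 0.14 for all genes, adjusted p = 0.0309). Mmp9, a protease of osteoclasts, was the 1 member past the threshold adjusted over the list alone, with 9.22 ± 0.28 in control and 10.76 ± 0.60 in knockout arrays (SD, n = 3 each, limma adjusted p = 0.203), and it passed over all genes with the deposited scaling (adjusted p = 0.000113). Ctsk, the protease of resorbing osteoclasts, differed by 0.11 ± 0.13 (SE), and by 0.03 to 0.26 with 1 array left out.

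Mdk, the heparin-binding growth factor midkine, was 1.61-fold higher, at 8.65 ± 0.07 in control and 9.33 ± 0.09 in knockout arrays (SD, n = 3 each, limma adjusted p = 0.133). Sostdc1, an antagonist of BMP and Wnt signalling, was 1.53-fold higher, at 5.79 ± 0.21 and 6.40 ± 0.18 (SD, n = 3 each, limma adjusted p = 0.315). Both passed adjusted over the list alone, which is no independent evidence because the study's own report is recalled to have singled out this pair. Mdk passed without control replicate 2 (adjusted p = 0.0223).

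Wnt ligands and receptors were higher for 19 and lower for 6 of 25 genes, and 3 passed adjusted over the list alone against 0 over all genes. The list passed camera with a preset correlation (adjusted p = 0.00589) but not with an estimated one (adjusted p = 0.313 with an estimated correlation). Wnt9a was 1.82-fold, Rspo3, which enhances Wnt signalling, 1.82-fold, and Fzd1, a Wnt receptor, 1.47-fold higher. Rspo3 and Wnt9a passed over all genes without control replicate 2 (limma adjusted p = 0.0134 and 0.0175), and Wnt9a with the deposited scaling (adjusted p = 0.0428). Wnt antagonists were higher for 12 and lower for 4 of 16, with a median of 0.16 (camera, adjusted p = 0.108), and 0 passed adjusted over the list alone. Among them Dkk3 and Shisa2 differed by 0.32 each, while Dkk1 differed by -0.70. Over all genes without control replicate 2, Sfrp2 passed as higher (0.87, limma adjusted p = 0.0107) and Dkk1 as lower (-0.93, 0.0134). Wnt target genes were higher for 11 and lower for 5 of 16, with a median of 0.14 and 0 past the threshold adjusted over the list alone (camera, adjusted p = 0.116, and 0.0303 without control replicate 2, where it was 0.433 with an estimated correlation). Their median was 0.04 without control replicate 3 and 0.06 without knockout replicate 1. Ccnd1, a cyclin of the G1 phase, differed by 0.34 ± 0.13 and Tnfrsf19 by 0.42 ± 0.17 (SE). With 1 array left out these ran from 0.24 to 0.45 and from 0.26 to 0.58.

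Chondrocyte markers had a median log2 difference of 1.33 and passed camera with a preset correlation (adjusted p = 1.12e-10) but not with an estimated one (adjusted p = 0.397 with an estimated correlation). Adjusted over the list alone, 10 were higher and 1 lower, against 0 over all genes. Groups were separated for those 11 genes, and Acan, Cnmd and the 3 collagen IX genes passed over all genes without control replicate 2. With the deposited scaling 8 of the list passed over all genes, all higher. Cnmd, the cartilage glycoprotein chondromodulin, had 7.38 ± 0.38 in control and 9.62 ± 0.77 in knockout arrays (SD, n = 3 each, limma adjusted p = 0.183). Col9a3 and Col9a2, chains of cartilage collagen IX, differed by 1.73 ± 0.24 and 1.42 ± 0.24 (SE). Col11a2, a collagen XI chain, was the lower member, by -0.41 ± 0.11 (SE). The level of the list ran from -1.11 in control replicate 2 to -0.09 in control replicate 1, and from 0.05 in knockout replicate 3 to 0.92 in knockout replicate 2 (2-sided exact permutation p = 0.1, the smallest that 3 arrays against 3 allow). Hedgehog and PTHrP genes, which guide cartilage growth, were higher for 6 and lower for 1 of 7, with a median of 0.32. Of these, 2 passed adjusted over the list alone, Ptch1 (0.37 ± 0.10, SE) and Gli1 (0.42 ± 0.13, SE), both targets of Hedgehog signalling. The list passed camera with a preset correlation (adjusted p = 0.00594), and not with the estimate (adjusted p = 0.313 with an estimated correlation). Its call also ended with the filter of 60% (adjusted p = 0.0738) and with the mean of all probe sets (adjusted p = 0.0536).

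**Figure D2:**
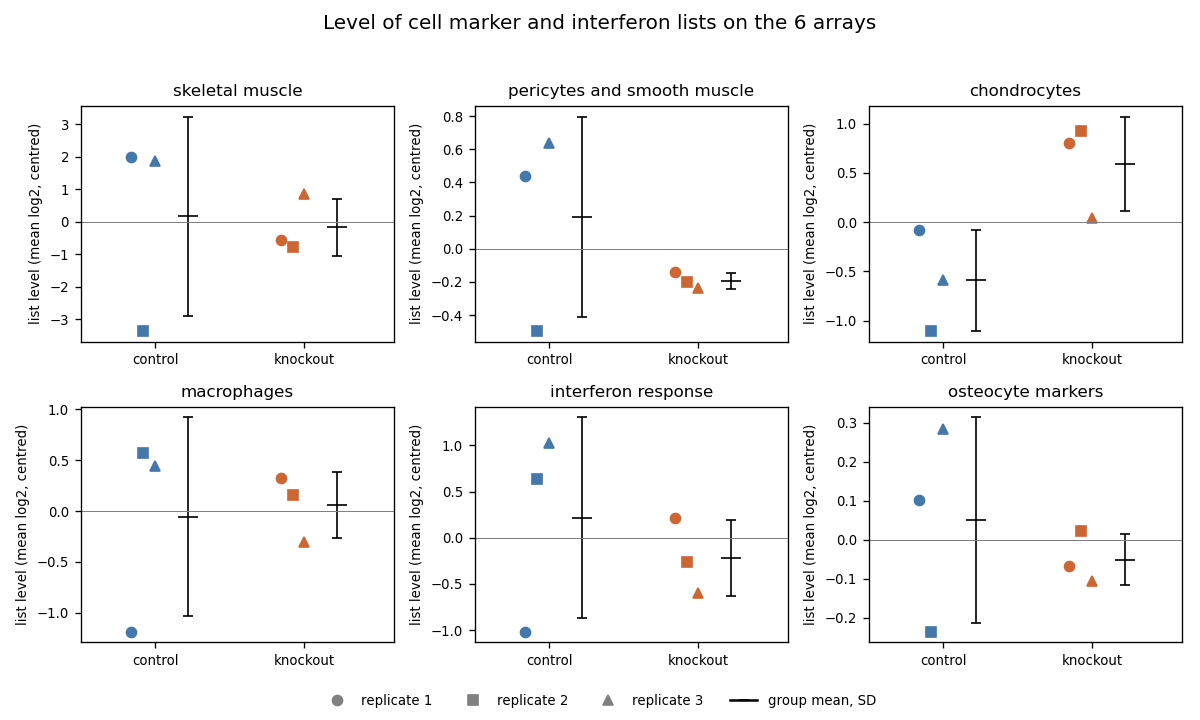
Level of 6 gene lists on each array, as the mean log2 value of a list's tested genes after each gene was centred over the 6 arrays, with 1 point per array and bars for the group mean and SD (n = 3). Skeletal muscle genes stood at -3.36 in control replicate 2, macrophage genes at -1.19 in control replicate 1, and chondrocyte genes were higher on every knockout array than on any control array.

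Extracellular matrix genes were higher for 20 and lower for 7 of 27, and passed camera with a preset correlation (adjusted p = 0.00221) but not with an estimated one (adjusted p = 0.313 with an estimated correlation). The 5 that passed adjusted over the list alone, against 0 over all genes, were all higher: Col12a1 (0.79 ± 0.12), Mfap2 (0.65 ± 0.11), Vcan (0.45 ± 0.09), Tnc (0.42 ± 0.10) and Ogn (0.52 ± 0.13, SE). Col12a1, Ogn, Tnc and Mfap2 passed over all genes without control replicate 2 (adjusted p = 0.0134, 0.0134, 0.0233 and 0.0379), and Mfap5 passed there as lower (-1.50, 0.00569). Growth factor genes were higher for 16 and lower for 8 of 24 (camera with a preset correlation, adjusted p = 0.00407, and adjusted p = 0.397 with an estimated correlation). Adjusted over the list alone 2 passed, against 0 over all genes: Igfbp3, which binds insulin-like growth factors (1.00 ± 0.20), and Ptn, pleiotrophin (0.50 ± 0.11, SE). Without control replicate 2 the list's call ended (adjusted p = 0.0656), while Igfbp3, Ptn and Igf1r passed over all genes as higher (adjusted p = 0.0279, 0.0223 and 0.0279) and Fgf1 and Igfbp6 as lower (-0.90 and -0.95, adjusted p = 0.0241 and 0.0139). Axon guidance genes were higher for 14 and lower for 9 of 23, with a median of 0.14 (camera with a preset correlation, adjusted p = 0.0152, and adjusted p = 0.313 with an estimated correlation). The ephrin receptors Epha3, Epha4 and Epha7 and the ephrin Efna1 were the 4 higher members that passed adjusted over the list alone, against 0 over all genes, and the call ended without control replicate 3 (adjusted p = 0.102), with the filter of 60% (0.0513) or with the mean of all probe sets (0.0609). Efna5 and Epha4 passed over all genes without control replicate 2 (0.86 and 0.76, adjusted p = 0.0134 and 0.0416). BMP and TGF-beta genes were higher for 18 and lower for 11 of 29, with 0 past the threshold adjusted over the list alone and a median of 0.05 (camera, adjusted p = 0.116, and 0.0403 with the deposited scaling at a median of 0.20, against 0.14 for all genes). Ltbp2 differed by 1.01 ± 0.26, Tgfb2 by 0.51 ± 0.15 and Bambi, a decoy receptor, by -0.32 ± 0.08 (SE). Ltbp2 passed over all genes with the deposited scaling (adjusted p = 0.0239), and Bmp4 and Id1 passed as lower without control replicate 2 (-0.75 and -0.69, adjusted p = 0.0405 and 0.0370). Matrix proteases and their inhibitors were higher for 12 and lower for 8 of 20, with Mmp9 alone past the threshold adjusted over the list alone and a median of 0.08 (camera, adjusted p = 0.230, and 0.0255 without control replicate 2, where it was 0.433 with an estimated correlation). The list was also called with the deposited scaling (0.24, against 0.14 for all genes, adjusted p = 0.0292), and its median was -0.02 without control replicate 1. Mechanosensing genes were higher for 8 and lower for 5 of 13, with 0 passing adjusted over the list alone (camera, adjusted p = 0.396), among them Panx3 at 0.45 and the ion channel Piezo1 at 0.33.

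Notch genes were lower for 7 and higher for 3 of 10, with a median of -0.07 (camera, adjusted p = 0.142). With the deposited scaling this median was 0.08, below that of all genes. Without control replicate 2 the list was called (-0.21, adjusted p = 0.00969, and adjusted p = 0.433 with an estimated correlation), as with array weights (-0.12, adjusted p = 0.0329), while its median was 0.01 without control replicate 3 or knockout replicate 2. Without control replicate 2 Notch3 passed over all genes (adjusted p = 0.0177). The list's level was 0.21, -0.18 and 0.23 in control replicates 1, 2 and 3, and moved with that of pericyte and smooth muscle genes (0.44, -0.50 and 0.64) and of skeletal muscle genes (2.00, -3.36 and 1.87). In knockout replicates 1, 2 and 3 it was -0.01, -0.20 and -0.04. Pericyte genes had -0.14, -0.20 and -0.24 there, and muscle genes -0.58, -0.77 and 0.84. Adjusted over the list alone 2 were lower, against 0 over all genes: Notch3, a receptor of mural cells (-0.62 ± 0.16), and Nrarp (-0.58 ± 0.16, SE). Estrogen response genes were higher for 11 and lower for 8 of 19, with a median of 0.04 and 0 past the threshold adjusted over the list alone (camera, adjusted p = 0.261). Igf1, insulin-like growth factor 1, differed by 0.52 ± 0.17 and Rerg by -0.36 ± 0.13 (SE). Nuclear receptors and coregulators were higher for 9 and lower for 4 of 13, with 0 past the threshold adjusted over the list alone (camera, adjusted p = 0.418), Ncoa3 at 0.33 and the estrogen-binding receptor Gper1 at -0.32.

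Ribosomal protein genes were higher for 15 and lower for 2 of 17, by a median of 0.11 (camera with a preset correlation, adjusted p = 0.00221, and adjusted p = 0.313 with an estimated correlation), and 0 passed adjusted over the list alone. Without control replicate 3 the median was 0.07. Rpl27 differed by 0.23 ± 0.06 (SE). Cholesterol synthesis genes were higher for 13 and lower for 1 of 14, by a median of 0.26 (camera with a preset correlation, adjusted p = 0.00589, and adjusted p = 0.562 with an estimated correlation). None of them passed adjusted over the list alone. Hmgcs1, an enzyme early in that pathway, differed by 0.41 ± 0.14 (SE). The list's level was 0.35 in knockout replicate 2 and -0.26 in control replicate 3, and its call ended when the former (median 0.12, adjusted p = 0.126) or the latter (adjusted p = 0.0751) was left out. Unfolded protein response genes were higher for 14 and lower for 6 of 20, with a median of 0.13 (camera with a preset correlation, adjusted p = 0.0152, and adjusted p = 0.507 with an estimated correlation). The chaperone Calr (0.38 ± 0.09) and the stress factor Ddit3 (0.48 ± 0.12, SE) were higher past the threshold adjusted over the list alone, against 0 over all genes, and the call ended without control replicate 1 (median 0.07, adjusted p = 0.0934) or knockout replicate 2 (adjusted p = 0.0843), or with the mean of all probe sets (0.126). Ddit3 passed over all genes without control replicate 2 (adjusted p = 0.0490). Oxidative phosphorylation genes were lower for 20 and higher for 7 of 27, by a median of -0.07 (camera with a preset correlation, adjusted p = 0.0446, and adjusted p = 0.671 with an estimated correlation). With the deposited scaling this median was 0.08, below that of all genes. The call ended in 9 of 19 alternatives, among them without control replicate 1 (median 0.00, adjusted p = 0.658), control replicate 3 (-0.03, 0.185) or knockout replicate 1 (-0.03, 0.429), and the median was -0.20 without control replicate 2. The list's level was 0.17, -0.14 and 0.11 in control replicates 1, 2 and 3, and moved with that of skeletal muscle genes (2.00, -3.36 and 1.87). In knockout replicates 1, 2 and 3 it was -0.13, 0.00 and -0.01, against -0.58, -0.77 and 0.84 for muscle genes. Uqcrb, of respiratory complex III, differed by -0.34 ± 0.09 (SE) and passed without control replicate 2 (adjusted p = 0.0333), as did Cycs, cytochrome c (-0.51, adjusted p = 0.0400), and 0 passed adjusted over the list alone. Glycolysis and hypoxia genes, immediate early and heat shock genes, apoptosis and p53 genes and cell cycle genes had medians of 0.06, 0.12, 0.01 and 0.02 (camera, adjusted p = 0.237, 0.270, 0.434 and 0.794), and 0 passed adjusted over each list alone. The immediate early and heat shock list was called with the deposited scaling by camera with the preset correlation (0.29, against 0.14 for all genes, adjusted p = 0.00696). In the main fit it had adjusted p = 0.657 by camera with an estimated correlation. Over all genes without control replicate 2, Fosb (0.82, limma adjusted p = 0.0333) and Ier2 (0.44, 0.0347) passed as higher and Adm (-0.68, 0.0334), Rhob (-0.58, 0.0221) and Ccng1 (-0.86, 0.0135) as lower. The cell cycle list was called at 0.25 without control replicate 1 (adjusted p = 0.00764) and at -0.21 without control replicate 2 (adjusted p = 0.0116), with adjusted p = 0.806 and 0.559 with an estimated correlation.

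Interferon response genes were lower for 16 of 16, by a median of -0.49, yet none had separated groups or passed adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 0.0387) and not with the estimate (adjusted p = 0.668 with an estimated correlation). Its level was -1.02, 0.64 and 1.03 in control replicates 1, 2 and 3 and 0.22, -0.26 and -0.60 in knockout replicates 1, 2 and 3. The call ended without control replicate 2 (median -0.31, adjusted p = 0.413), control replicate 3 (-0.08, 0.797), knockout replicate 2 (-0.51, 0.0843) or knockout replicate 3 (-0.24, 0.207), or with the filter of 60% (0.0652), and the median was -1.13 without control replicate 1. Macrophage markers moved with it in control replicate 1, at -1.19, against 0.57 and 0.44 in the other controls. Of 20 macrophage markers 13 were higher and 7 lower, with a median of 0.07 (camera, adjusted p = 0.270). The list was called at -0.50 without control replicate 1 (adjusted p = 1.90e-06), and at 0.37, 0.34 and 0.27 without control replicate 2, control replicate 3 or knockout replicate 3 (adjusted p = 0.0110, 0.0356 and 0.0380). In this order these 4 calls had adjusted p = 0.582, 0.578, 0.746 and 0.661 with an estimated correlation. H2-Ab1, a class II antigen-presenting chain, was the member past the threshold adjusted over the list alone, at 5.84 ± 0.08 in control and 6.68 ± 0.10 in knockout arrays (SD, n = 3 each, limma adjusted p = 0.160), and it passed over all genes without control replicate 2 (adjusted p = 0.0286).

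Skeletal muscle markers differed most between arrays of 1 group. Myl1, a myosin light chain, had log2 levels of 13.07 and 13.18 in control replicates 1 and 3, of 5.94 in control replicate 2 and of 10.47, 10.39 and 12.22 in knockout replicates 1, 2 and 3. The list was lower for 9 and higher for 5 of 14, with a median of -0.30 (camera, adjusted p = 0.396) and 0 passing adjusted over the list alone, and was called without control replicate 2 (median -2.37, adjusted p = 5.52e-12, and adjusted p = 0.433 with an estimated correlation). The list was also called with all arrays under the deposited scaling (-0.18, adjusted p = 0.00241) and with array weights (-0.75, adjusted p = 0.0290), both by camera with the preset correlation. In the main fit the list had adjusted p = 0.811 by camera with an estimated correlation. Its direction turned with single arrays, to medians of 0.52 without control replicate 1 and 0.36 without control replicate 3 (adjusted p = 0.544 and 0.585). Actn3 (-2.60, limma adjusted p = 0.0165), Myh1 (-2.64, 0.0344), Acta1 (-2.41, 0.0388) and Des (-1.05, 0.0363) passed over all genes without control replicate 2. Pericyte and smooth muscle genes, the group of Rgs5, were lower for 8 and higher for 1 of 9 (camera with a preset correlation, adjusted p = 0.0205, and adjusted p = 0.657 with an estimated correlation). Their level in control replicate 2 was -0.50, against 0.44 and 0.64 in the other controls, and Rgs5 alone passed adjusted over the list alone, against 0 over all genes. The call ended without control replicate 1 (median -0.21, adjusted p = 0.192), control replicate 3 (-0.11, 0.209) or knockout replicate 2 (-0.41, 0.0562), and the median was -0.79 without control replicate 2, where Acta2 (-0.82, adjusted p = 0.00569), Myh11 (-1.52, 0.0133), Tagln (-0.95, 0.0139) and Mcam (-0.74, 0.0431) passed over all genes.

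Among other cell types, endothelial markers were higher for 11 and lower for 4 of 15 (median 0.14, camera, adjusted p = 0.159), with Erg at 0.62 past the threshold adjusted over the list alone. Neuron and glia markers had a median of 0.32 over 6 genes (camera, adjusted p = 0.116), and S100b, which cartilage also expresses, passed at 0.86 adjusted over the list alone. Neutrophil, adipocyte, suture mesenchyme and fibroblast, epithelium, and platelet markers had medians of -0.17, -0.31, -0.05, -0.01 and 0.06 (camera, adjusted p = 0.116, 0.116, 0.622, 0.708 and 0.722), with 0 passing adjusted over each list alone. With the deposited scaling the medians of the mesenchyme and epithelium lists were 0.11 and 0.13, below that of all genes. Lymphocyte, erythroid and mast cell markers had 2 tested genes each and no list test, with medians of -0.28, 0.25 and -0.06. Of these, the transferrin receptor Tfrc alone, at 0.59, passed adjusted over the list alone. Without control replicate 2 the adipocyte and mesenchyme lists were called (medians -0.58 and -0.13, adjusted p = 0.00215 and 0.0116), while the mesenchyme median was 0.06 without control replicate 1. In control replicates 1, 2 and 3 their levels (0.29, -0.27 and 0.48 for adipocytes, 0.40, -0.42 and 0.28 for mesenchyme) moved with that of skeletal muscle genes (2.00, -3.36 and 1.87). In knockout replicates 1, 2 and 3 adipocyte genes had -0.06, -0.23 and -0.20, and mesenchyme genes -0.06, -0.15 and -0.04. Muscle genes had -0.58, -0.77 and 0.84 there. Over all genes without control replicate 2, S100b and Tfrc passed as higher (limma adjusted p = 0.00899 and 0.0286). Passing as lower were the endothelial markers Tek (-0.83, 0.0283) and Esam (-0.95, 0.0298), the neuron marker Map2 (-0.68, 0.0424), the adipocyte markers Lpl (-0.77, 0.00880) and Fabp4 (-0.58, 0.0360), and 6 fibroblast markers, among them Clec3b (-2.23, 0.00268), Mfap5 (-1.50, 0.00569) and Pi16 (-1.60, 0.0201). The endothelial list was called without control replicate 3 or knockout replicate 3 (adjusted p = 0.0356 and 0.0366), the neutrophil list without control replicate 3 or knockout replicate 1 (0.0356 and 0.0218), and the neuron and glia list without knockout replicate 3 (0.0296). None of these calls with 1 array left out held with an estimated correlation (smallest adjusted p = 0.402). With all arrays, the deposited scaling called the neuron and glia, neutrophil and adipocyte lists (adjusted p = 0.0439, 0.0310 and 0.0338). The mean of all probe sets called the neuron and glia list (0.0483), and array weights or the muscle covariate the adipocyte list (0.0290 and 0.0477). The replicate block called the neutrophil list (-0.17, adjusted p = 0.0208). The neuron and glia median was 0.18 without control replicate 2 and 0.61 without knockout replicate 3. The neutrophil median was -0.07, -0.36, -0.32 and -0.01 without control replicate 1, control replicate 3, knockout replicate 1 or knockout replicate 2. The platelet median was -0.05 without knockout replicate 1 and 0.18 without knockout replicate 3, and the endothelial median 0.06 and 0.24 without control replicates 2 and 3.

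**Figure D3:**
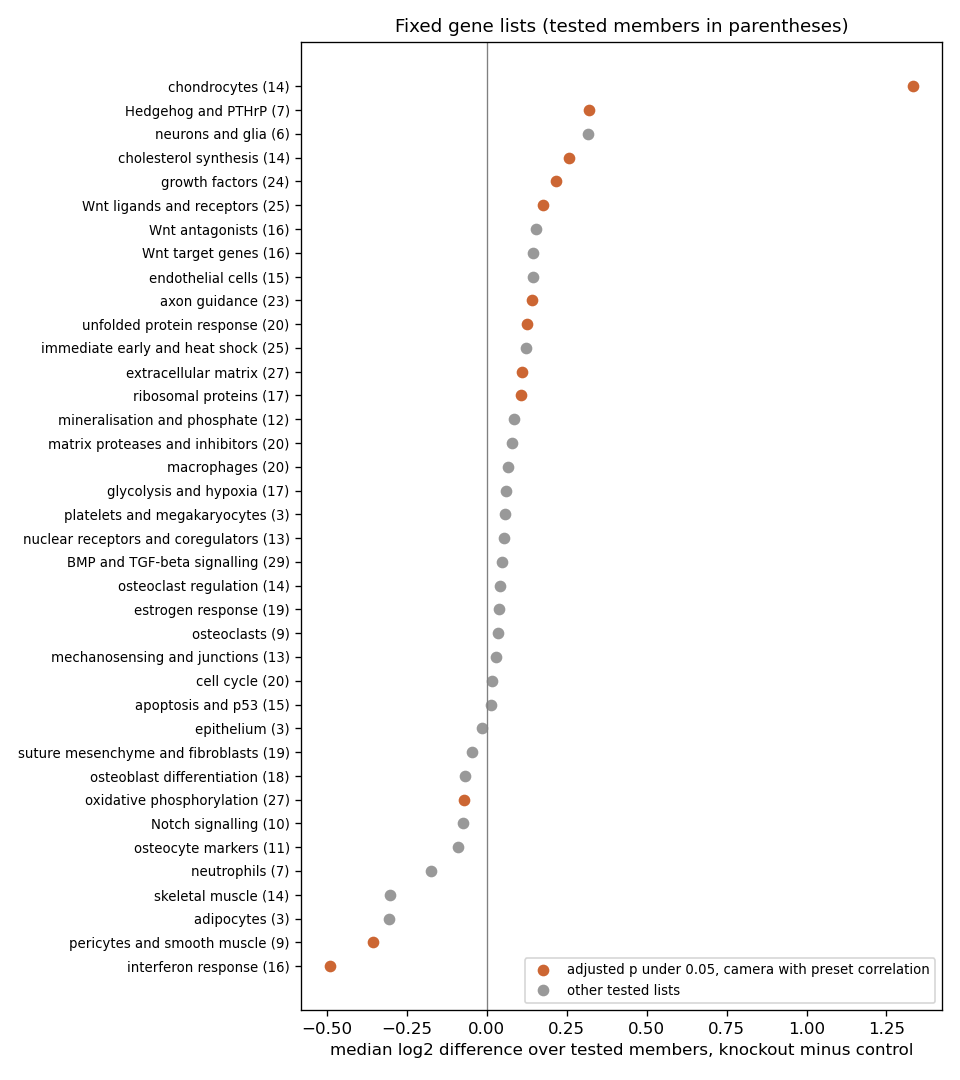
Median log2 difference, knockout minus control, of the 38 tested gene lists, with the number of tested genes in parentheses. Coloured points mark the 12 lists past an adjusted p of 0.05 by camera with a preset correlation, from 1.33 for chondrocytes to -0.49 for the interferon response, and none of them passed with an estimated correlation.

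Together 12 of 38 lists passed camera with a preset correlation, 9 higher and 3 lower, and their median, mean and test had the same sign. With an estimated correlation 0 passed and 5 had an unadjusted p under 0.05. Leaving out 1 array in turn gave 75 list calls with the preset correlation, and 0 of these passed with an estimated correlation. Calls under the deposited scaling, array weights, the mean of all probe sets, the replicate block or a covariate were not tested with an estimated correlation. Small medians of lists that were not called moved with 1 array left out, as for estrogen response (0.01 to 0.09), nuclear receptors (-0.02 to 0.12), osteoclast regulation (0.04 to 0.14), mineralisation (0.04 to 0.11) and immediate early genes (0.05 to 0.13). Fry's directional test gave 0 (smallest adjusted p = 0.0714) and its mixed test 10.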

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

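The covariate fits, the joint change of scaling and arrays and the estimated correlation with 1 array left out were chosen only after the results were seen. With 6 arrays, limma gave 0 higher and 0 lower genes, and it did so with either offset, median subtraction, other filters, the mean of probe sets, each probe set on its own, other variance models, array weights, a minimum fold or a threshold of 0.1. With the deposited scaling 30 were higher and 0 lower, and 19 lists passed. Leaving out 1 array in turn gave 0 to 86 higher and 0 to 212 lower genes, 8 to 20 lists, and -0.27 to -0.16 for Esr1. Control replicate 2 was the array whose removal gave 86, 212 and 20, and leaving out any other array gave 0 higher and 0 lower genes. With the muscle level as a covariate 28 were higher and 18 lower, and with the macrophage level 3 were higher and 0 lower. With the deposited scaling and without control replicate 2, 113 were higher and 135 lower. The cause was not tested, except for muscle content as below. Of the 46 genes called with the muscle covariate, 43 were among the 298 called without control replicate 2, as were 18 of the 30 called with the deposited scaling.

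Of the 12 lists, 0 passed with an estimated correlation and 0 by fry. With an estimated correlation and 1 array left out, 0 lists passed whichever array it was. The chondrocyte, Wnt ligand, extracellular matrix and ribosomal lists, 4 of 12, passed in all 19 other alternatives. The macrophage list was called at -0.50 without control replicate 1 and at 0.37 without control replicate 2, and the cell cycle list at 0.25 without control replicate 1 and at -0.21 without control replicate 2. Of 163 named genes, 117 passed in no alternative, and 10 changed sign without a call under the deposited scaling. There the median of all genes moved from -0.01 to 0.14, a shift that can by itself turn the sign of small differences. Same-numbered arrays deviated with correlations of -0.38, 0.10 and -0.04, so no pairing by number was seen, though so few arrays cannot exclude it. With the number as a replicate block 0 genes were higher, 0 lower, 13 lists passed and Esr1 differed by -0.20. Dim signals limit what can be measured, since 38.6% to 46.9% of probe sets lay under 16.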

Other observations

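The tests of degraded RNA, of array scaling, of cartilage cells, of control replicate 2 alone and of other splits, and the genes named in the next paragraph, were chosen only after the results were seen. The tests on further muscle genes and on the muscle covariate were written down before their results.

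Past the threshold in all 3 of the fits without control replicate 2, with the deposited scaling and with the muscle covariate were 14 genes, and 9 of these were in no fixed list. They had to be higher in the knockout arrays, since the deposited scaling called 30 genes higher and 0 lower. Slc4a10, a sodium and bicarbonate transporter, had the largest difference among them, with 5.55 ± 0.71 in control and 7.83 ± 0.49 in knockout arrays (SD, n = 3 each, limma adjusted p = 0.183 with all arrays). Gpha2, a glycoprotein hormone subunit, had 6.54 ± 0.55 and 8.16 ± 0.04. Col8a2, a collagen VIII chain, had 9.44 ± 0.55 and 10.42 ± 0.02 (SD, n = 3 each). Egfl6, Alcam and Ecrg4 differed by 1.04, 1.02 and 1.01.

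Muscle transcripts were far lower in control replicate 2, by a median of -6.05 on the log2 scale over the fixed list. Degraded RNA in that array stays open by its 3' to 5' signal ratio. This ratio was the highest for beta-actin (1.93, 1.17 times the highest of the others) and for Gapdh (0.889 against 0.684 to 0.802). The bounds for this test were set, and 1 of them revised, after the values were seen. Osteoblast genes did not share the fall: their list level there was 0.09, against -0.06 to 0.01 on the other arrays. This argues against a loss of RNA in general. Skeletal muscle cells collected in unequal amounts remain a candidate explanation. The sort for Dmp1-driven fluorescence does not exclude them, since its gate held 0.8% to 1.0% of cells in unmarked mice, against 10% to 15% in marked mice. Of 15 further muscle genes tested, 53.3% were lowest in control replicate 2, against 21.9% of all genes, short of the 90% set in advance for this explanation, and above the 50% set against it. Their median difference from the other controls was -0.93, where more than 1 unit was asked for, so the test does not decide. These genes were dim, at 8.21 or less on every control array. With the log offset they could not show a fall as large as that of the fixed list. No biological explanation was tested, since the array shares its genotype with the other controls.

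The absence of any gene past the threshold may come from uneven muscle content, which widens the spread among controls. With the muscle level as a covariate 46 genes passed, between the 10 that would have argued against this and the 50 set for it, so it cannot be told apart from other sources of spread. The 46 genes included 2 higher and 1 lower member of the muscle list. Its mean is the covariate, so those calls are not independent of it. The real split of the arrays gave 0 genes past the threshold and the highest other 0, so all 10 splits had to reach it and that count says nothing. The 10 splits are too few for a share under 0.05: at an unadjusted p under 0.05 the real split gave 1151 genes and the highest other 793 (1 split as large), and for lists 12 and 16 (3 splits as large). The split with 16 lists set control replicates 1 and 3 with knockout replicate 3, the 3 arrays with the most muscle RNA, against the rest.

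Cartilage genes were higher in the knockout arrays. Array scaling is argued against by list medians of 1.45 with the deposited scaling and 1.31 with array medians subtracted. With the other offsets included, the lowest median was 0.85. The array medians differed by only 0.36 on the log2 scale, so rescaling could hardly have removed a median of 1.33. Control replicate 2 alone is argued against by a median of 1.05 without it. Cartilage cells collected in unequal amounts may add to the pattern, and the sort does not exclude them. Over 14 genes, the difference between the groups and the difference of knockout replicates 1 and 2 from replicate 3 had a Spearman rho of 0.618, between the bounds of 0.8 and 0.5. Against the difference of control replicates 1 and 3 from replicate 2 the rho was 0.486, and the abundant marker Col11a2 was lower. The differences behind the first rho share the knockout arrays and grow with a gene's abundance on the linear scale. That rho can therefore be positive with or without such cells. With 14 genes these values do not decide, so such cells and an effect of the genotype on the osteocytes cannot be told apart here, and the genotype stays open as untested.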
